A study of Homo sapiens with 4 samples.

How the data were processed

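Total RNA of BT474 cells treated for 24 h with vehicle or 0.5 mM AICAR was labelled with biotin and hybridised to Affymetrix U133 Plus 2.0 arrays, per the labels' protocols, with 2 arrays per group. The deposited values are log2 expression values per probe set, already normalized by the authors; Affymetrix Expression Console was used, per the submitters' processing notes, and its version, its summarization algorithm and its background correction are not given in the sources used here. The values ran from 2.95 to 15.3 (log2) and were used as deposited. Because the background correction is unknown, changes of dim probe sets may be compressed; probe intensities were not used here. For arrays, their number sets the precision; the median standard error of a log2 difference was 0.0772.

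The array holds 54675 probe sets, of which 62 are controls. The platform annotation listed 42898 probe sets, 41097 with 1 gene symbol and 1801 with several, and left 11721 other probe sets without a listed gene. Symbols of 41043 single-symbol probe sets were updated through their Entrez IDs with the RefSeq gene table of GRCh38.p14, which was used for names only, and no coordinates are given. For each of 19775 genes the probe set with the highest mean over the 4 arrays was used; 10523 genes had more than 1 probe set. Genes whose mean lay below the 30th percentile of gene means (log2 6.11) were left out as dim, which left 13842 genes. Some genes, including 2 of those fixed by name, are not reported here.

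Differences, AICAR minus vehicle, were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3) without a trend, with Benjamini-Hochberg adjustment over the genes tested; rose, fell, higher and lower are used of genes with an adjusted p under 0.05, two-sided. With 2 arrays per group an exact permutation test of a single gene cannot give a p below 0.333, so none was used. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and beside it with camera at an estimated correlation, which no list passed, and with fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The estimated correlation and its test rest on 2 residual degrees of freedom, so failing it does not by itself show correlation within a list. The lists covered the folate cycle, serine synthesis and uptake, de novo purine synthesis, pyrimidine and deoxynucleotide synthesis, the methionine cycle and polyamines, PGC-1 and ERR regulators, oxidative phosphorylation, the TCA cycle, fatty acid oxidation, glycolysis, cholesterol synthesis and uptake, fatty acid synthesis, DNA replication, mitosis, p53 targets, the integrated stress response, autophagy and lysosome, AMPK subunits and relatives, ribosome biogenesis, luminal and estrogen receptor genes, the ERBB2 amplicon, NRF2 and oxidative stress, the interferon response, and stromal, endothelial and blood cell markers. They held 520 different genes, of which 479 had a single-symbol probe set and 453 were tested.

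The lists, the tests, the alternatives and the rule for genes named in the text were set before the data were examined. The rule took the 12 called genes with the largest rise and the 12 with the largest fall whose AICAR values both lay outside the vehicle range, a fixed set of genes of folate, serine and purine metabolism with PPARGC1A, ESRRA, ERBB2 and ESR1, and up to 4 called members of each list with the largest change, or the 2 members with the largest change where none was called. Other genes named in the text, among them IDI1, MKI67 and ULK1, were chosen after their values were seen. The alternatives were no dim filter or one at the 50th percentile, quantile normalization or median centring of the deposited values, eBayes with a trend and robust variances, the mean of all probe sets of a gene, all probe sets tested separately, an adjusted p under 0.1, a bound of 1.5-fold, the replicate number as a block, and each array left out in turn.

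The fit was tested on simulated data for AICAR against vehicle, with 2 against 2 arrays, 13842 genes, 200 of them changed, in 20 simulations. It recovered 51.8% of genes changed by 0.5 and 97.6% of genes changed by 1 on the log2 scale, and 4.83% of its calls were false. A list of 20 genes shifted by -0.3 was called in 100% of simulations with either correlation, and an unchanged list in 5% with the preset and 0% with the estimated correlation. A simulated list counted as called at an unadjusted camera p under 0.05, whereas real lists needed an adjusted p under 0.05. These rates therefore do not give the power of the adjusted tests, with either correlation. The simulated genes were independent of each other. Their noise was normal, with variances drawn from the prior that limma fitted, so a false share near the threshold was likely in advance. A smaller share of genes was changed than the 9.82% called in the data, so recovery in the data may differ.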

Results

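Gene expression was profiled on Affymetrix U133 Plus 2.0 arrays in BT474 cells, an established human breast cancer line with amplified ERBB2 (HER2). The cells had been treated for 24 h with vehicle or with 0.5 mM AICAR, a nucleoside analog that is phosphorylated in cells to ZMP, an intermediate of purine synthesis and an AMP mimic that activates the energy sensor kinase AMPK. There were 2 arrays per group and 4 in all. The arrays had similar distributions, with medians over 54675 probe sets of 6.37 and 6.38 (log2) in the vehicle group and 6.40 and 6.38 in the AICAR group. Across probe sets, the replicate arrays correlated at r = 0.997 in both groups, and arrays of different groups correlated at r = 0.994 to 0.995; probe sets are not independent replicates. The leading principal component held 70.1% of the variance and separated the groups, with vehicle arrays at -13.4 and -12.1 and AICAR arrays at 12.1 and 13.5. The number of arrays limits the precision of every value that follows. Nothing in the labels says that the replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

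The comparison of AICAR with vehicle asked which transcripts changed after treatment with this AMPK activator. The RNA with the largest rise was LINC01133, a long non-coding RNA, which went from 6.43 ± 0.06 (log2, SD, n = 2) to 9.18 ± 0.18, a 6.71-fold increase (SE 0.0995 on the log2 scale, limma adjusted p = 0.000893); its other probe set differed by 0.39. TGFBI, a secreted matrix protein, was 3.56-fold higher (log2 1.83, SE 0.142, adjusted p = 0.00477), and the type II keratin KRT80 was 2.69-fold higher (log2 1.43, SE 0.142, adjusted p = 0.00669). PIP, a secreted protein of apocrine and luminal breast cells, rose by 1.40 (log2, SE 0.0692, adjusted p = 0.00278). VIM, the intermediate filament of mesenchymal cells, rose from 10.51 to 11.75 (log2 difference 1.24, SE 0.0699, adjusted p = 0.00303), while its other probe set differed by 0.05. The other genes among the 12 largest rises were SAMD4A (log2 1.41), CYP4X1 (1.38), KYNU (1.38), FILIP1L (1.25), the antisense RNA KANSL1-AS1 (1.24), the histone gene H2AC8 (1.22) and COSMOC (1.21). The lowest of the other probe sets differed by 0.10 for SAMD4A, 0.18 for KYNU, -0.01 for FILIP1L and 0.12 for KANSL1-AS1, and FILIP1L did not pass without vehicle replicate 2 (adjusted p = 0.0578). The only called member of the stromal, endothelial and blood cell markers was the collagen gene COL1A1, which moved opposite to VIM and TGFBI at -0.63 (log2).

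The largest fall among the called genes was that of the zinc finger gene ZNF91, 2.69-fold lower with AICAR (log2 -1.43, SE 0.0893, adjusted p = 0.00320). Only 2 of its 7 probe sets shared that sign, and the mean of all its probe sets differed by -0.06 (adjusted p = 0.562). IVNS1ABP was 2.53-fold lower (log2 -1.34, adjusted p = 0.00303), with 3 of 4 probe sets of the same sign. Its remaining probe set went the other way, at 0.55. SLC7A11, the cystine transporter that supplies glutathione synthesis, was 2.46-fold lower (log2 -1.30, SE 0.137, adjusted p = 0.00776), and all 3 of its probe sets were negative. The RNA-binding proteins SYNCRIP (log2 -1.28, 6 of 7 probe sets negative) and PTBP2 (log2 -1.16) fell. So did ZNF678 (-1.16), FAM117B (-1.11) and the homologous recombination factor RAD51AP1 (-1.07). The list ended with the protease inhibitor TFPI2 (-1.03), ST20-AS1 (-0.93), the regulatory protein kinase A subunit PRKAR2B (-0.90) and CA8 (-0.90). The highest of the other probe sets differed by 0.03 for ZNF678, 0.02 for FAM117B, -0.27 for TFPI2 and -0.0023 for CA8. ST20-AS1 did not pass without vehicle replicate 1 (adjusted p = 0.136) or without vehicle replicate 2 (0.0777).

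**Figure D1:**
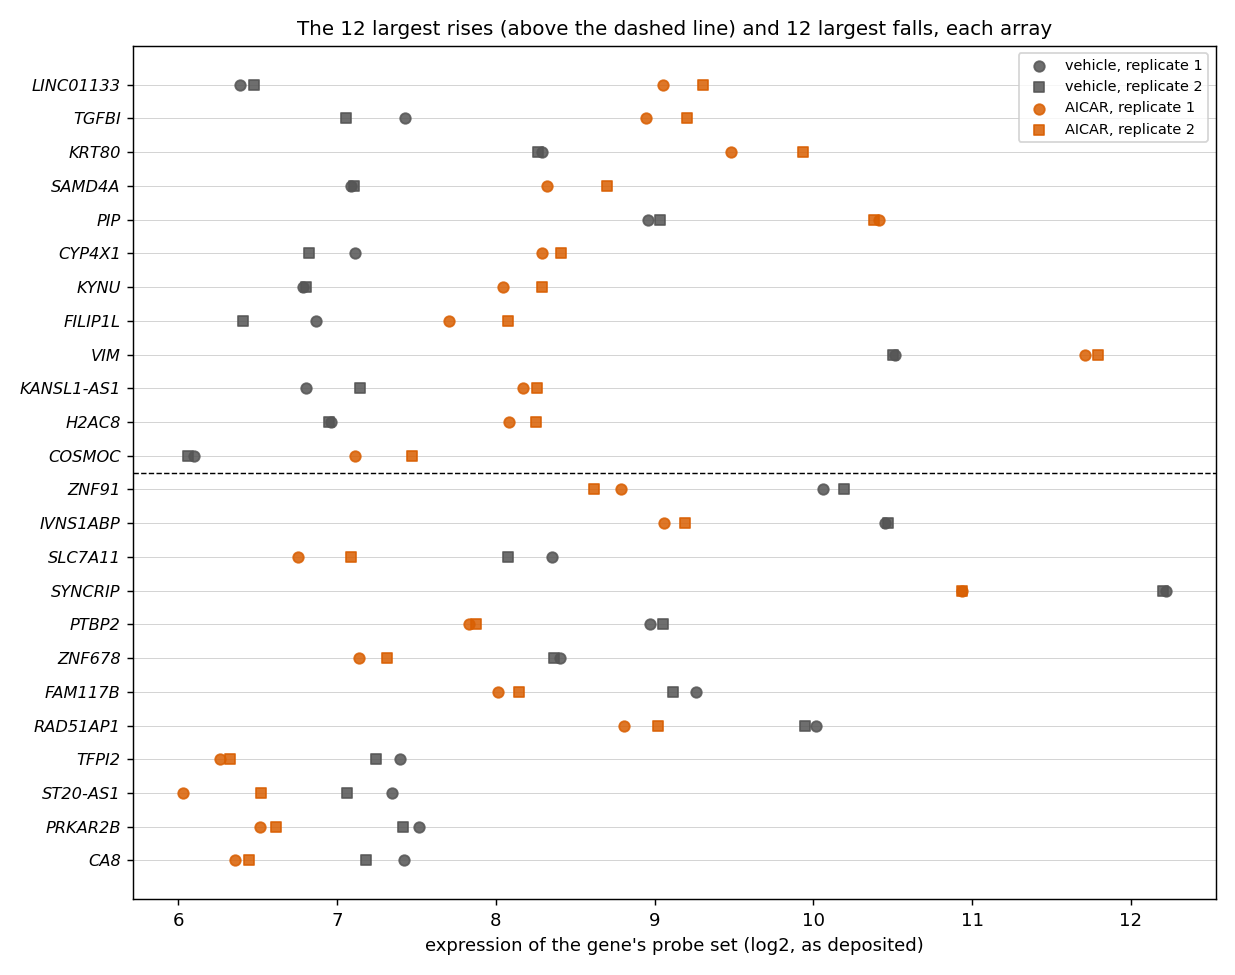
Expression (log2, as deposited, horizontal axis) of the 12 genes with the largest rise, above the dashed line, and the 12 with the largest fall, with 1 point per array. In each gene both AICAR arrays lie on the same side of both vehicle arrays. LINC01133 shows the widest gap, 2.75 on the log2 scale.

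Of 13842 genes tested, 641 were higher and 718 lower with AICAR at an adjusted p under 0.05 (limma), 9.82% of the genes tested, against 1775 and 1841 at an unadjusted p under 0.05. At least 1.5-fold changes were found in 179 higher and 120 lower genes, and at least 2-fold changes in 28 and 9. With the mean of all probe sets of a gene, 1307 of the 1318 called genes that were tested kept their sign and 902 kept their call. Quantile normalization of the deposited values turned the split to 854 higher and 624 lower, and moderation with a trend and robust variances called 1107 and 1359. The counts fell in each fit that left out 1 array, and more so without a vehicle array, where the spread comes from the AICAR pair alone. On the second principal component, with 17.6% of the variance, the AICAR arrays lay at -9.01 and 8.67 and the vehicle arrays at 2.27 and -1.93. Without vehicle replicate 1 there were 90 higher and 30 lower genes, and without vehicle replicate 2 there were 69 and 51. Without AICAR replicate 1 there were 553 and 432, and without AICAR replicate 2 there were 266 and 362. The log2 differences in these fits correlated at r = 0.942 to 0.959 with those from all 4 arrays, with which they share 3 arrays.

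The series is about the PGC-1/ERR axis and folate-dependent metabolism, and the genes of the folate cycle were the main list. Of 19 tested members, 0 rose and 1 fell (limma), both over all genes tested and adjusted over the list alone, against 2 higher and 4 lower at an unadjusted p under 0.05. The member that fell was MTRR, which keeps methionine synthase in its active state, at 10.43 ± 0.01 (log2, SD, n = 2) with vehicle and 9.87 ± 0.06 with AICAR, 1.48-fold lower (SE 0.0693, adjusted p = 0.0102). The cytosolic trifunctional enzyme MTHFD1 differed by -0.20 (log2, 95% confidence interval -0.37 to -0.04, adjusted p = 0.114) and its mitochondrial relative MTHFD2 by -0.07 (-0.25 to 0.11, adjusted p = 0.598). Thymidylate synthase TYMS differed by -0.09 (-0.26 to 0.08, adjusted p = 0.472) and mitochondrial serine hydroxymethyltransferase SHMT2 by -0.02 (-0.20 to 0.16, adjusted p = 0.884). All probe sets of these 4 genes were negative, and the lowest differed by -0.27 for MTHFD1, -0.30 for MTHFD2, -0.42 for TYMS and -0.32 for SHMT2. With the mean of all probe sets TYMS (adjusted p = 0.0819), MTHFD2 (0.170) and SHMT2 (0.201) did not pass, nor did MTHFD1. SHMT1 lay below the bound for dim genes and, in a fit of all genes, differed by 0.10 (log2, adjusted p = 0.547). As a group, 12 members had negative and 7 positive differences, with a median of -0.07 and a mean of -0.07 (log2; camera adjusted p = 0.250; adjusted p = 0.492 with an estimated correlation). The median was -0.11 without vehicle replicate 1, -0.03 without AICAR replicate 1, -0.02 without the dim filter and -0.05 with the mean of all probe sets. The camera adjusted p at the preset correlation was 0.106 to 0.527 over the other settings, and fry, which compares with no other genes, gave 0.0947. With a trend and robust variances 3 members fell, MTHFD1 among them (adjusted p = 0.0130). Without vehicle replicate 1 and without vehicle replicate 2, 0 members passed, and the adjusted p of MTRR was 0.0730 and 0.0747, while its difference stayed at -0.57 and -0.56. SHMT2 was 0.01 (log2) after quantile normalization and 0.04 without vehicle replicate 1.

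The 8 genes of serine synthesis and uptake, which feed carbon units to folate, had 0 members past the threshold (limma), over all genes and adjusted over the list alone, and 1 lower member at an unadjusted p under 0.05. PSAT1, a serine synthesis aminotransferase, differed by -0.26 (log2, SE 0.0823, adjusted p = 0.107), the mitochondrial serine carrier SFXN1 by -0.17 (adjusted p = 0.202; 2 of 3 probe sets negative) and PHGDH, which opens the serine pathway, by 0.05 (adjusted p = 0.768). The list median was -0.12 (camera adjusted p = 0.380), but -0.04 without vehicle replicate 2, -0.08 without AICAR replicate 1 and -0.0084 with the mean of all probe sets. Among 12 genes of de novo purine synthesis, IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis, rose 1.45-fold (log2 0.54, SE 0.0664, adjusted p = 0.0102) and 0 fell, with the same counts adjusted over the list alone. ATIC, the enzyme that uses AICAR monophosphate as its substrate, differed by 0.17 (log2, adjusted p = 0.190), and the trifunctional enzyme GART by -0.20 (adjusted p = 0.147). The 9 probe sets of GART ranged from -0.83 to 0.21, and 8 of them were negative. The purine list had a median and a mean of 0.01, while camera placed it lower than other genes (adjusted p = 0.943). The median was -0.09 with the mean of all probe sets, where 1 member rose and 2 fell. It was also negative without vehicle replicate 1 (-0.02) and AICAR replicate 1 (-0.04), but 0.04 without AICAR replicate 2 and 0.05 after quantile normalization. The test fry, which does not compare it with other genes, gave a rise (adjusted p = 0.0115). The fall of PSAT1 passed with the mean of all probe sets (log2 -0.31, adjusted p = 0.0294) and with a trend and robust variances (0.0103). So did that of GART (0.0320 and 0.0475), and ATIC rose with a trend and robust variances (0.0339). IMPDH2 did not pass without vehicle replicate 1 (adjusted p = 0.0749) or without vehicle replicate 2 (0.0747). The difference of PHGDH was -0.02 without vehicle replicate 2 and -0.03 without AICAR replicate 1.

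**Figure D2:**
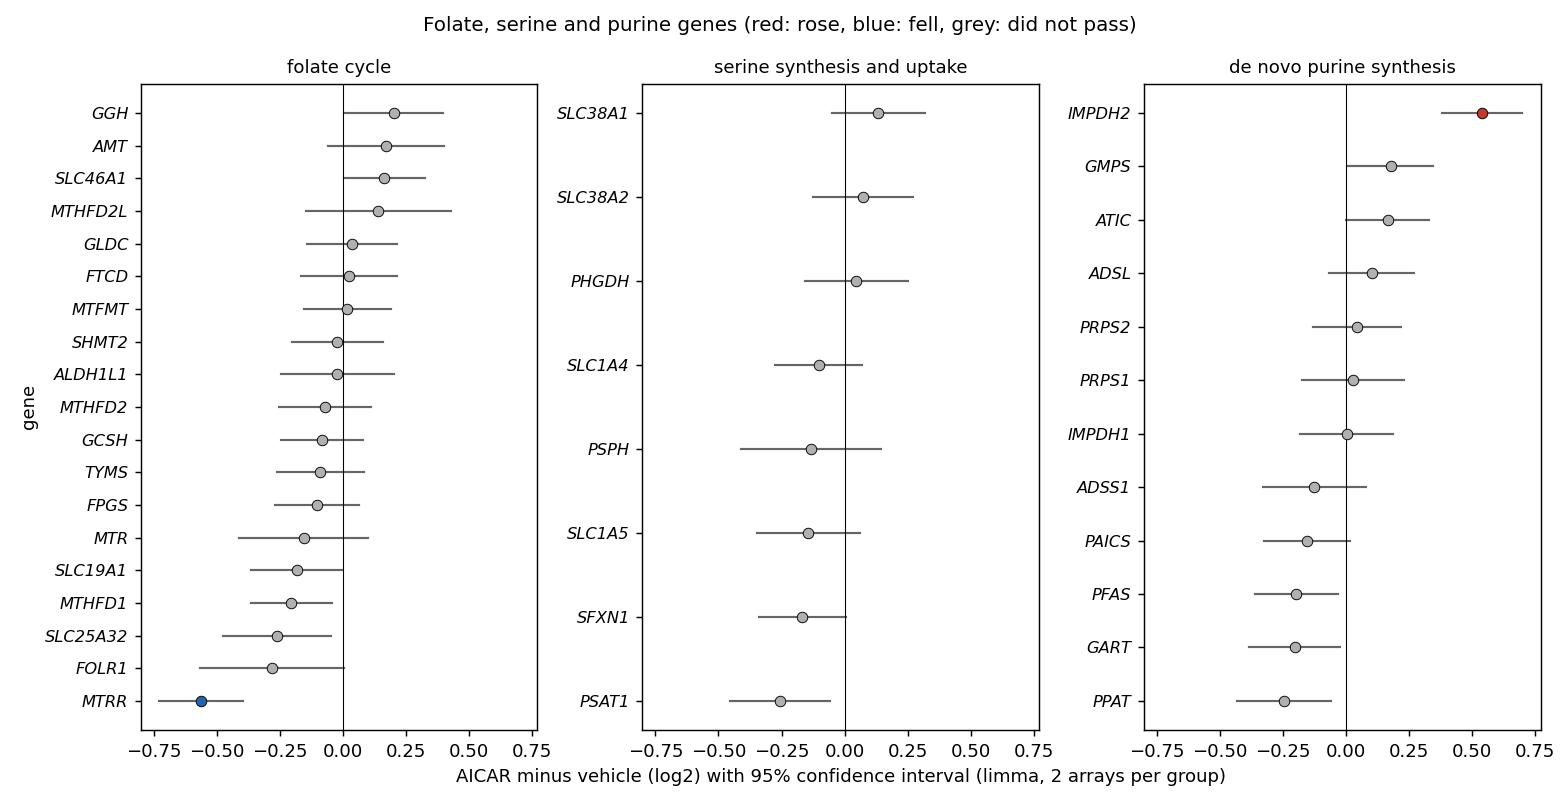
Difference between AICAR and vehicle (log2, horizontal axis) for each tested gene of the folate, serine and purine lists, with its 95% confidence interval from limma over 2 arrays per group. Red points rose, blue points fell and grey points did not pass the threshold. MTRR at -0.56 and IMPDH2 at 0.54 are the coloured points.

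Of 14 genes of pyrimidine and deoxynucleotide synthesis 0 rose and 3 fell (5 adjusted over the list alone), namely the ribonucleotide reductase subunit RRM2 (log2 -0.54, SE 0.0705, adjusted p = 0.0118), CTP synthase CTPS1 (-0.41, adjusted p = 0.0247) and dihydroorotate dehydrogenase DHODH (-0.35, adjusted p = 0.0330). The list median was -0.17 (camera adjusted p = 0.00240; adjusted p = 0.256 with an estimated correlation). In the methionine cycle and polyamine list, 4 of 12 members fell and 0 rose, with the same counts adjusted over the list alone. They were CTH (log2 -0.49) and CBS (-0.31), the enzymes that turn homocysteine into cysteine, the polyamine enzyme ODC1 (-0.46) and the S-adenosylmethionine synthetase MAT2A (-0.37). The 3 probe sets of CBS ranged from -0.88 to 0.08. The list median was -0.13 (camera adjusted p = 0.00589; adjusted p = 0.256 with an estimated correlation). Without the filter on dim genes CTPS1, DHODH, MAT2A and CBS did not pass (adjusted p = 0.0507, 0.0678, 0.0670 and 0.0892), nor did CBS after quantile normalization (0.0515) or with the replicate block (0.0638), or CTH with the mean of its probe sets (0.0725). With a trend and robust variances 7 pyrimidine genes fell. In both lists 0 members passed without vehicle replicate 1 or without vehicle replicate 2, 1 and 3 passed without AICAR replicate 1, and 2 and 2 without AICAR replicate 2.

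The regulators that the series title names did not pass the threshold. PPARGC1A, which encodes PGC-1α, was at 6.54 ± 0.02 (log2, SD, n = 2) with vehicle and 6.75 ± 0.01 with AICAR, a difference of 0.22 (95% confidence interval 0.06 to 0.37, adjusted p = 0.0978). Its level was close to the bound for dim genes of 6.11. ESRRA, which encodes ERRα, differed by 0.10 (-0.06 to 0.26, adjusted p = 0.397), and its 2 probe sets had opposite signs, with a mean of -0.01. Of 11 PGC-1 and ERR regulators 0 passed (limma), over all genes and adjusted over the list alone, while 1 was higher and 2 lower at an unadjusted p under 0.05 and 1 fell with a trend and robust variances. The respiratory gene regulator NRF1 differed by -0.27 (adjusted p = 0.125), with 3 of 5 probe sets negative, and the list median was -0.10 (camera adjusted p = 0.369), but -0.04 without AICAR replicate 1 and -0.18 without AICAR replicate 2.

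Among the mitochondrial and energy lists, the oxidative phosphorylation genes showed few changes. Of 69 members, 2 rose and 0 fell, with the same counts adjusted over the list alone: the complex I subunit NDUFA7 (log2 0.42, adjusted p = 0.0249) and COX7A2L (0.40, adjusted p = 0.0219), a factor of respiratory supercomplexes. Their median was 0.05 (camera adjusted p = 0.228), but 0.02 without vehicle replicate 1 and 0.0012 with the mean of all probe sets. In the TCA cycle 1 of 14 members fell, the isocitrate dehydrogenase subunit IDH3A (log2 -0.31, adjusted p = 0.0399; also 1 adjusted over the list alone), while the list had a median of 0.01, a mean of -0.04 and a camera direction of lower (adjusted p = 0.574). With the mean of all probe sets the median of the TCA list was -0.08, and it was -0.0089 without vehicle replicate 1. In fatty acid oxidation 2 of 16 members fell and 0 rose, also adjusted over the list alone, namely the medium-chain dehydrogenase ACADM (log2 -0.51, SE 0.0718, adjusted p = 0.0138) and the electron carrier ETFDH (-0.34, adjusted p = 0.0315). The median was -0.10 (camera adjusted p = 0.0211; adjusted p = 0.256 with an estimated correlation), and the list did not pass without vehicle replicate 2 (0.0686) or without AICAR replicate 2 (0.0635). In glycolysis 1 of 20 members fell (3 adjusted over the list alone) and 0 rose. It was the glucose transporter SLC2A1 (log2 -0.40, adjusted p = 0.0205), which with the mean of its 2 probe sets did not pass (adjusted p = 0.257). Of the 20 differences 18 were negative, with a median of -0.10 (camera adjusted p = 0.00646; adjusted p = 0.256 with an estimated correlation). With a trend and robust variances 11 oxidative phosphorylation genes rose and 2 fell, and 7 glycolysis genes fell. In these 4 lists 0 members passed without vehicle replicate 1 or 2, 1, 0, 1 and 1 passed without AICAR replicate 1, and 0, 0, 1 and 0 without AICAR replicate 2. Without the dim filter NDUFA7 (adjusted p = 0.0507), IDH3A (0.0825) and ETFDH (0.0664) did not pass, nor did IDH3A after quantile normalization (0.0506) or with the replicate block (0.0628), or IDH3A (0.0748) and ETFDH (0.0712) with the mean of their probe sets.

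Cell cycle genes formed the largest group of falls among the lists. Of 30 mitosis genes 18 fell and 0 rose (26 adjusted over the list alone), and 29 of the 30 differences were negative, with a median of -0.36 (camera adjusted p = 1.52e-15; adjusted p = 0.253 with an estimated correlation). The anaphase activator CDC20 was 1.82-fold lower (log2 -0.86, SE 0.0962, adjusted p = 0.00813), the spindle protein HMMR 1.60-fold (-0.68, adjusted p = 0.00646), the ubiquitin-conjugating enzyme UBE2C 1.56-fold (-0.64, adjusted p = 0.00920) and cyclin B1, CCNB1, 1.51-fold (-0.59, adjusted p = 0.00874). The single positive difference, that of the proliferation marker MKI67, was 0.13 and did not pass; with the mean of its probe sets it was -0.36 (adjusted p = 0.0513). Of 32 DNA replication genes 15 fell and 0 rose (17 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 3.97e-08; adjusted p = 0.253 with an estimated correlation). The licensing factor CDC6 was lower by 1.59-fold (log2 -0.67, adjusted p = 0.00953), and the replicative helicase genes MCM5 (-0.64) and MCM7 (-0.56) and the initiation factor MCM10 (-0.59) fell too. Without vehicle replicate 1, 1 mitosis gene and 0 replication genes fell, and without vehicle replicate 2, 0 and 0 did, against 13 and 12 without AICAR replicate 1 and 10 and 9 without AICAR replicate 2. The list medians stayed between -0.38 and -0.35 and between -0.32 and -0.29 in those fits.

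Of 18 genes of cholesterol synthesis and uptake 5 rose and 0 fell (8 rose adjusted over the list alone): the sterol sensor partner INSIG1 (log2 0.58, SE 0.0866, adjusted p = 0.0161), squalene epoxidase SQLE (0.46), MSMO1 (0.45), SC5D (0.40) and IDI1 (0.31). The median was 0.18 (camera adjusted p = 0.00484; adjusted p = 0.256 with an estimated correlation). Fatty acid synthesis genes had no common direction, with a median of -0.04 over 12 members (camera adjusted p = 0.574). FASN, the fatty acid synthase, was 1.58-fold lower (log2 -0.66, SE 0.0721, adjusted p = 0.00793) and the lipogenic regulator THRSP was higher (log2 0.41, adjusted p = 0.0362), the only members called (2 rose and 1 fell adjusted over the list alone). FASN's other probe set differed by 0.13, and with the mean of both FASN did not pass (adjusted p = 0.0649), nor did SC5D (0.300) or IDI1 (0.408). Without the dim filter SC5D (0.0512), IDI1 (0.0874) and THRSP (0.0678) did not pass, and 3 cholesterol genes rose. IDI1 did not pass with the replicate block (0.0620) or with any of the 4 arrays left out (0.0836 to 0.217). Rises in the cholesterol list numbered 8 with a trend and robust variances, 0 without vehicle replicate 1 or 2, 5 without AICAR replicate 1 and 2 without AICAR replicate 2. FASN did not pass without vehicle replicate 2 (adjusted p = 0.0597), and THRSP not without vehicle replicate 1 (0.204), vehicle replicate 2 (0.107) or AICAR replicate 2 (0.0974).

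Of 25 integrated stress response genes 1 rose and 6 fell (1 and 13 adjusted over the list alone). The list median was -0.19 (camera adjusted p = 0.000374; adjusted p = 0.256 with an estimated correlation). SLC7A11 fell most, followed by the cysteinyl-tRNA synthetase CARS1 (log2 -0.47, adjusted p = 0.0153) and ATF4, the transcription factor of this response (-0.42, adjusted p = 0.0201), while the amino acid transporter chain SLC3A2 rose (0.49, adjusted p = 0.0158). Of 18 p53 targets 3 rose and 1 fell (3 and 3 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.574). That median was -0.0046 without vehicle replicate 2, -0.03 with the dim filter at the 50th percentile and 0.07 without AICAR replicate 2. The stress cytokine GDF15 (log2 0.59, adjusted p = 0.0234), TP53I3 (0.54) and CCNG1 (0.34) rose, and the DNA repair gene DDB2 fell (-0.28, adjusted p = 0.0487). Among 14 NRF2 and oxidative stress genes the efflux pump ABCC2 rose (log2 0.48, adjusted p = 0.0209) and SLC7A11, which is in both lists, fell; 2 rose and 1 fell adjusted over the list alone. Their median was 0.08, their mean -0.02 and the camera direction higher (adjusted p = 0.533); the median was 0.03 without AICAR replicate 1. With the mean of all probe sets GDF15 (adjusted p = 0.0912) and CARS1 (0.0701) did not pass, and without the dim filter CCNG1 (0.0757) and DDB2 (0.1001) did not, nor did DDB2 after quantile normalization (0.0711). Falls in the stress response list numbered 12 with a trend and robust variances, 1 without vehicle replicate 1, 1 without vehicle replicate 2, 5 without AICAR replicate 1 and 3 without AICAR replicate 2. SLC3A2 did not pass without vehicle replicate 1 (adjusted p = 0.109) or vehicle replicate 2 (0.0865). With the replicate block CCNG1 (0.0510) and DDB2 (0.0819) did not pass. Of the p53 targets, 0 passed without vehicle replicate 1 or 2, and ABCC2 did not pass without vehicle replicate 1 (adjusted p = 0.110), vehicle replicate 2 (0.116) or AICAR replicate 2 (0.0568).

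Of 29 autophagy and lysosome genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00240; adjusted p = 0.256 with an estimated correlation). The autophagosome protein WIPI1 was 1.91-fold higher (log2 0.94, SE 0.0916, adjusted p = 0.00646), the Rag GTPase RRAGD 1.69-fold (0.76, adjusted p = 0.0272), the sialidase NEU1 1.57-fold (0.65, adjusted p = 0.00776) and the protease CTSL 1.51-fold (0.60, adjusted p = 0.0115). The kinase ULK1 was the member that fell (-0.34, adjusted p = 0.0421), but it did not pass without the dim filter (0.0826) or with any of the 4 arrays left out (0.0552 to 0.237). RRAGD did not pass without vehicle replicate 2 (0.107) or AICAR replicate 2 (0.0818). Of 13 AMPK subunits and relatives 3 rose and 0 fell, also adjusted over the list alone. They were the arrestin domain proteins TXNIP (log2 0.66, adjusted p = 0.00776) and ARRDC4 (0.61, adjusted p = 0.0154), which are not subunits, and the AMPK gamma subunit PRKAG1 (0.48, adjusted p = 0.0137). The median of this list was 0.01 (camera adjusted p = 0.380; fry adjusted p = 0.0322), and -0.06, -0.07, -0.0030 and 0.07 without vehicle replicate 1, vehicle replicate 2, AICAR replicate 1 and AICAR replicate 2. In ribosome biogenesis 1 of 23 members rose and 3 fell (1 and 5 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00262; adjusted p = 0.256 with an estimated correlation). The transcription factor MYC rose (log2 0.46, adjusted p = 0.0176), and UTP4 (-0.45), POLR1A (-0.36) and NOP58 (-0.33) fell. Without the dim filter these falls did not pass (adjusted p = 0.0523, 0.0575 and 0.0938), nor did POLR1A with the mean of its probe sets (0.169) or NOP58 after quantile normalization (0.0565) or with the replicate block (0.0694). With a trend and robust variances 2 members rose and 9 fell. Rises in the autophagy list numbered 5 without the dim filter, 2 without vehicle replicate 1, 1 without vehicle replicate 2, 6 without AICAR replicate 1 and 3 without AICAR replicate 2. In the AMPK list 1 and 0 rose without vehicle replicate 1 and 2, and the ribosome list had 0 members past the threshold without vehicle replicate 1, vehicle replicate 2 or AICAR replicate 2.

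ERBB2 itself was at 13.31 ± 0.01 (log2, SD, n = 2) with vehicle and 13.36 ± 0.00 with AICAR, a difference of 0.05 (95% confidence interval -0.11 to 0.21, adjusted p = 0.693). Its 3 probe sets ranged from -0.08 to 0.47, and with their mean it did not pass (adjusted p = 0.196). Of the 10 amplicon genes 0 passed (limma), over all genes and adjusted over the list alone, against 3 higher and 1 lower at an unadjusted p under 0.05 and 2 higher with a trend and robust variances. The amplicon neighbours PNMT and PGAP3 differed by -0.25 and 0.22, and the list median was 0.06 (camera adjusted p = 0.336; fry adjusted p = 0.0322). Of 16 luminal and estrogen receptor genes 3 fell and 0 rose, also adjusted over the list alone: the transcription factor MYB (log2 -0.53, adjusted p = 0.0173), carbonic anhydrase CA12 (-0.44, adjusted p = 0.0197) and ESR1, the estrogen receptor (-0.31, adjusted p = 0.0411). For ESR1, 5 of 9 probe sets were negative. It did not pass without the dim filter (adjusted p = 0.0845), after quantile normalization (0.0586), with the replicate block (0.0609), with the mean of its probe sets (0.773) or without any of the 4 arrays in turn. The luminal list had a median of -0.09 (camera adjusted p = 0.106; fry adjusted p = 0.00897; camera adjusted p = 0.0246 without the dim filter). The median was -0.04 without vehicle replicate 2 and -0.06 without AICAR replicate 2. With a trend and robust variances 2 members of this list rose and 5 fell. Falls numbered 0 without vehicle replicate 1 or 2, 2 without AICAR replicate 1 and 1 without AICAR replicate 2. Of 12 interferon response genes 0 passed (limma), over all genes and adjusted over the list alone, against 2 lower at an unadjusted p under 0.05. IFI6 differed by -0.36 (adjusted p = 0.0927) and USP18 by -0.26 (adjusted p = 0.104), which passed with a trend and robust variances (0.0470 and 0.0393). The list had a median of 0.01, a mean of -0.03 and a camera direction of lower (adjusted p = 0.694). The median was -0.02 without vehicle replicate 2 and with the mean of all probe sets.

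Of the stromal, endothelial and blood cell markers, 9 of the 16 with a probe set lay above the bound for dim genes. COL1A1 fell (log2 -0.63, SE 0.106, adjusted p = 0.0209; also 1 adjusted over the list alone) and 0 rose. With the mean of its 5 probe sets COL1A1 did not pass (adjusted p = 0.0727), nor without vehicle replicate 1 (0.0868) or 2 (0.110). The list had a median of 0.01, a mean of -0.07 and a camera direction of lower (adjusted p = 0.528; fry adjusted p = 0.0310). The median was -0.05 without vehicle replicate 1, -0.10 without vehicle replicate 2, -0.06 without AICAR replicate 1 and -0.29 with the dim filter at the 50th percentile.

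**Figure D3:**
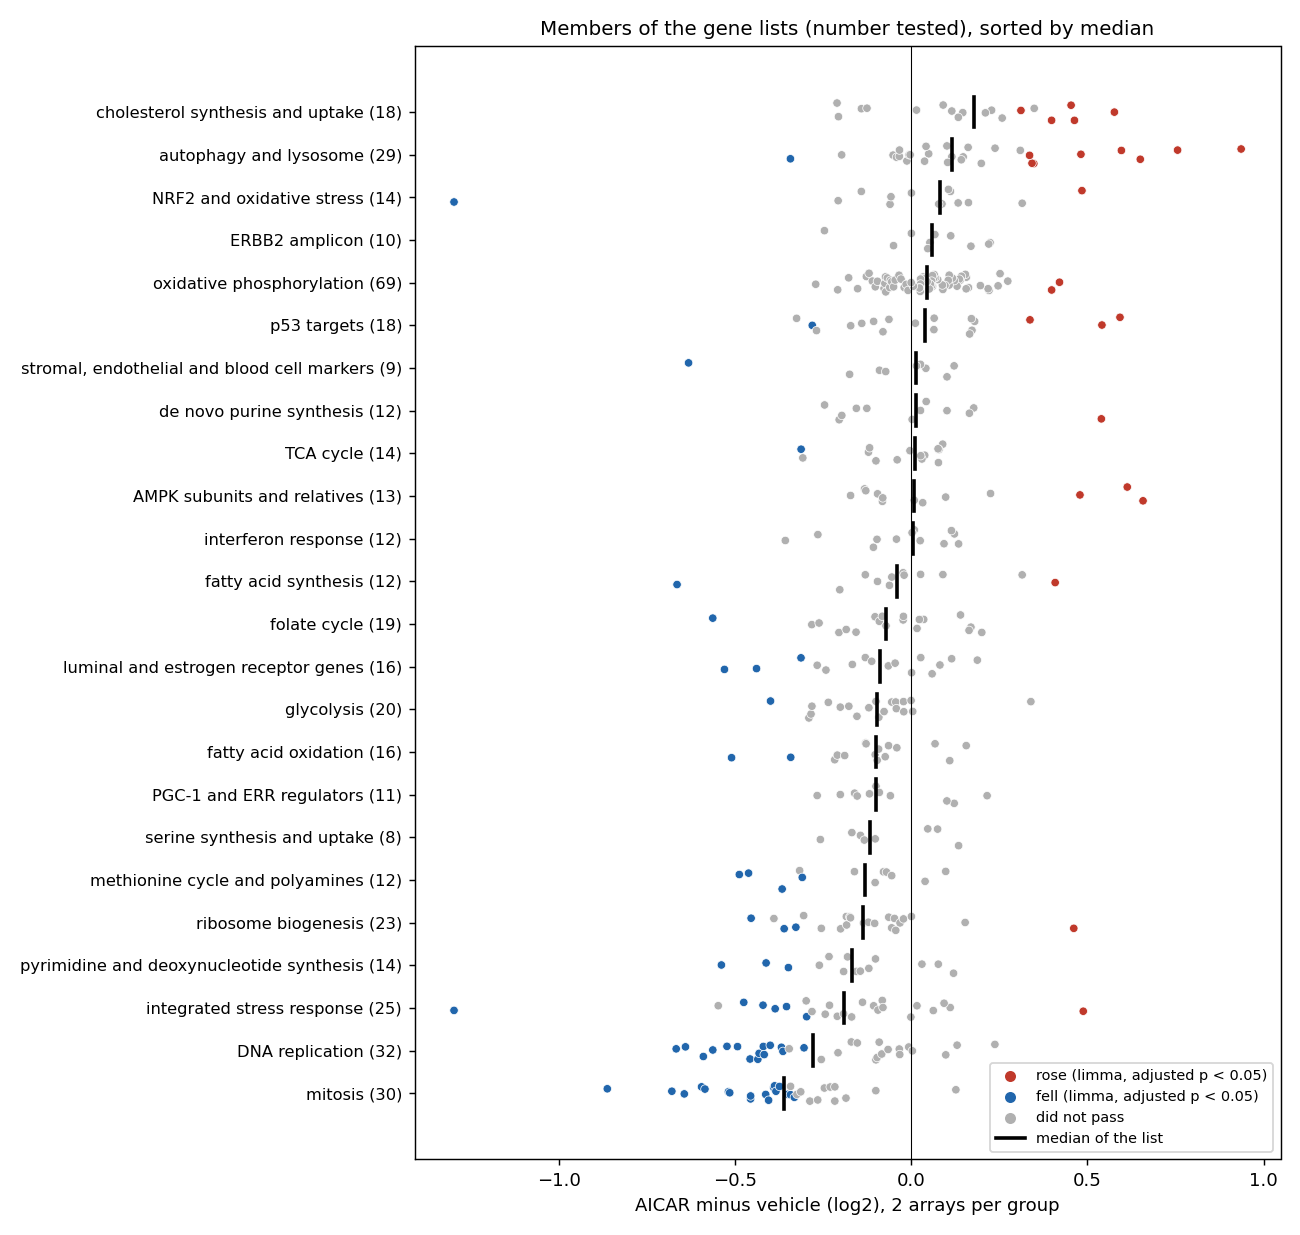
Difference between AICAR and vehicle (log2, horizontal axis, 2 arrays per group) for each tested member of the 24 gene lists, sorted by list median, which is the black bar. Red points rose, blue points fell and grey points did not pass. The medians run from 0.18 in cholesterol synthesis and uptake to -0.36 in mitosis.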

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

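Of the 11721 probe sets without a listed gene, which enter no comparison above, 3857 lay at or above the dim bound. Among all 11721, dim ones included, 19 were higher and 70 lower with AICAR (limma over all non-control probe sets, adjusted p under 0.05). These calls lie outside the gene comparison. For scale, 401 of the 41097 single-symbol probe sets were higher and 540 lower in a separate fit, a larger share. No explanation was tested for the calls without a listed gene.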

How the results depend on the processing

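The counts of higher and lower genes moved with these settings. Without the dim filter 368 genes were higher and 355 lower, with more genes tested. A trend and robust variances gave 1107 and 1359, for which the cause was not tested. An adjusted p under 0.1 gave 1093 and 1173, and a bound of 1.5-fold gave 179 and 120, by their construction. All probe sets tested separately gave 401 higher and 540 lower probe sets. Leaving out each array in turn, with fewer samples and the lone array of a group assumed to vary like the other group, gave 69 to 553 higher and 30 to 432 lower genes. The replicate block moved them by less than 1.5 times, to 577 higher and 586 lower genes; equal replicate numbers do not pair the samples in the labels, and the deviations of equally numbered arrays correlated at r = -0.0721 across genes. Of the 1359 called genes, 687 were also called without the dim filter, 1251 after quantile normalization, 1286 after median centring, 1336 with a trend and robust variances and 1103 with the replicate block. Of 76 named genes called, 61 kept their call without the dim filter, 71 after quantile normalization, 76 after centring, 64 with the mean of all probe sets, 70 with the replicate block, and 28, 23, 64 and 54 without vehicle replicate 1, vehicle replicate 2, AICAR replicate 1 and AICAR replicate 2; 0 changed sign after quantile normalization or with the mean of all probe sets. Results that did not pass changed sign as follows, and the cause was not tested: the purine list was higher with fry (adjusted p = 0.0115) and in 2 fits that leave out an array (range of all 4 fits 0.849 to 0.982), the stromal, endothelial and blood cell markers were higher without the dim filter (0.773), ESRRA was -0.0103 (log2) with the mean of its probe sets, SHMT2 was 0.00891 after quantile normalization and -0.0833 to 0.0393 with an array left out, PHGDH was -0.0260 to 0.120 with an array left out, and MKI67 was -0.36 with the mean of its probe sets. The 10 lists called with the preset correlation all lost their call with an estimated one. The estimates were 0.0123 for mitosis and -0.0125 for DNA replication, near or below the preset 0.01, with unadjusted camera p of 0.0147 and 0.0211. The highest estimate among the 10 was 0.0331, for autophagy and lysosome. That test rests on 2 residual degrees of freedom, so the loss does not show that genes within these lists move together. Signal over background could not be judged from summarised values.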

Other observations

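Chosen after the result was seen were the comparison of gene families, the count of probe sets called in opposite directions, and the tests on DNA replication genes, on 3' to 5' control signals and on histone probe sets with shared suffixes. Families of genes that share a symbol stem were searched. In all, 155 families of at least 10 tested genes were tested with camera, 15 passed, and 0 passed with an estimated correlation (adjusted p = 0.875 for each). Among the rises, 10 of 29 histone genes were higher and 0 lower (mean log2 0.29, median 0.11, camera adjusted p = 0.00220). H2AC8 was 2.32-fold higher, H2BC5 2.27-fold, H2AC25 2.21-fold (log2 1.15) and H2AC6 rose by 1.03 (log2). Of 29 cytochrome P450 genes 6 rose and 0 fell (median 0.13, adjusted p = 0.00220), among them CYP4X1 (log2 1.38), CYP4Z2P (1.09), CYP1A1 (1.02) and CYP4B1 (0.81). Of 20 dual-specificity phosphatase genes, which mostly act on MAP kinases, 7 rose and 1 fell (median 0.16, adjusted p = 0.0391), with DUSP1 at 0.74 and DUSP2 at 0.70. Of 13 annexin genes 4 rose (median 0.16, adjusted p = 0.0367), with ANXA1 at 0.95 and ANXA3 at 0.77. Each of these medians stayed positive after quantile normalization, after centring and with each array left out. Without vehicle replicate 1 and without vehicle replicate 2, 0 phosphatase genes passed, and 5 and 5 histone genes, 3 and 2 cytochrome genes and 2 and 1 annexin genes rose.

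Among the falls, 3 of 14 genes of the mitochondrial import family TIMM were lower, TIMM23B (log2 -0.56), TIMM8B (-0.44) and TIMM50 (-0.32). The family median was -0.24 (camera adjusted p = 0.00220; adjusted p = 0.875 with an estimated correlation of 0.0823). That median was -0.231 without vehicle replicate 1 and -0.214 without vehicle replicate 2. After quantile normalization 2 TIMM genes fell, and the family did not pass with fry (adjusted p = 0.128). In 2 of 139 genes with at least 2 called probe sets, the probe sets were called in opposite directions. MALAT1, a nuclear long non-coding RNA, had probe sets at -1.13, -0.84 and 1.12 (log2), and SMARCE1, a subunit of the SWI/SNF remodelling complex, at -0.59 and 0.73. The MALAT1 probe sets are all marked _x_at or _s_at, suffixes counted below as shared, and those of SMARCE1 have a plain suffix.

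The histone rise might come from probe sets shared between near-identical copies. The 21 probe sets with a plain suffix, which mark a single target by design, had a median of 0.107 (log2, 95% bootstrap interval 0.0347 to 0.184). Only 3 of them rose, so the rise was weaker there but not confined to the other suffixes. The interval resamples probe sets of the same arrays and leaves out the spread between arrays. It therefore cannot decide whether sharing is the whole cause. The 13 probe sets with a suffix counted here as shared (_s_at, _x_at or _a_at) had a median of 0.459 (0.0023 to 0.70), with 6 rises. That median is above that of the plain ones but with an overlapping interval, so how much sharing adds stays open. More cells copying DNA would raise the replication genes as well, and their median was -0.280 over 32 genes; arrest within S phase and a change in histone mRNA 3' ends were not tested, and an effect of AICAR stays open as a hypothesis.

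Of 365 ZNF genes 38 fell and 6 rose, with a median of -0.0600 (log2, camera adjusted p = 0.00719; adjusted p = 0.875 with an estimated correlation of 0.119). The median stayed negative after quantile normalization (-0.03) and centring (-0.07). It was -0.0394, -0.0817, -0.0380 and -0.0816 without vehicle replicate 1, vehicle replicate 2, AICAR replicate 1 and AICAR replicate 2. A drift of genes of low signal would lower other genes of like signal too. In these arrays, 10000 random lists matched on mean expression had medians of -0.00748 to 0.0306 in their middle 95%, so matched genes did not share the shift. Their genes were drawn separately, so this range leaves out correlation among ZNF genes and the spread between arrays. It therefore does not show that the ZNF median lies beyond chance. A choice of unusual probe sets, as for ZNF91, is argued against for the family within these arrays, since its 250 other probe sets had a median of -0.0545 (95% bootstrap interval -0.0954 to -0.0204). That interval resamples probe sets and leaves out the spread between arrays. Falls numbered 3 without vehicle replicate 1, 3 without vehicle replicate 2, 21 without AICAR replicate 1 and 29 without AICAR replicate 2, and fry gave an adjusted p of 0.299; an effect of AICAR is one hypothesis, and a shared property of these transcripts such as short half-life was not tested.

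For the lower mitosis and replication genes, RNA degradation with AICAR could lower signals, but the 3' minus 5' difference of the control probe sets moved by 0.0505 (log2) for ACTB, with AICAR arrays on both sides of the vehicle arrays, and by -0.0274 for GAPDH. After quantile normalization the median of the 62 genes was -0.314 (95% bootstrap interval -0.354 to -0.231). The deposited arrays already had medians of 6.37 to 6.40 (log2). The value therefore argues only against a remaining difference in scale, and the authors' own normalization was not tested. The interval resamples genes and leaves out the spread between arrays. A slower cell cycle with AICAR is a candidate explanation that these arrays do not test apart from other effects of the treatment. The 4 arrays make 3 splits into 2 and 2, too few for a share under 0.05. The real split, 1 of the 3, called 1359 genes, and the highest of the others 0. Each other split puts 1 vehicle and 1 AICAR array in each group. The treatment difference then enters its residual spread, so few calls were likely in advance and no conclusion is drawn from the 0.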
